A study of Mus musculus with 30 samples.

How the data were processed

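Astrocyte ribosome-bound RNA was measured in 30 libraries of wild-type Aldh1l1-TRAP mice, 6 from each of prefrontal cortex, dorsal striatum, ventral striatum, amygdala and hippocampus, with 3 per region in each of 2 batches named in the labels. Per the labels, each library held a pool of 2 animals for prefrontal cortex, dorsal striatum and hippocampus and of 6 animals for ventral striatum and amygdala. About 5 ng of immunoprecipitated RNA was amplified with the Ovation kit and made into TruSeq libraries. The labels call the libraries of a region technical replicates, so p-values measure the spread between these libraries, which may be partly technical. Samples of an Alzheimer's disease mouse model named in the study's title were not analysed here, since the table used holds no columns of them.

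The deposited table holds raw read counts of 38926 genes by symbol, in whole numbers, which the authors made with STAR 2.3.0e and HTSeq 0.9.1 per the submitters' processing notes. The genome build, the annotation and the strand setting are not given in the sources used here, so reads of overlapping genes on opposite strands could not be told apart. Total counts ran from 17768455 to 22961665 in batch 1 and from 6881770 to 8465670 in batch 2, and 19631 to 21041 and 15979 to 18249 genes had a count. Amplified reads are not independent molecules.

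Counts were scaled by TMM and genes kept by filterByExpr (minimum count 10, grouped by region), which left 15355 genes. Region and batch were fitted in edgeR 4.0.16 (R 4.3.3) by glmQLFit, and glmQLFTest gave for each gene an F test among the 5 regions, each region against the mean of the other 4 on the log scale, the 10 pairs of regions, batch 2 against batch 1, and the region by batch interaction. P-values were adjusted by Benjamini-Hochberg within each comparison at 0.05, two-sided. The SE of a fold change is its size divided by the square root of the F statistic. Levels are TMM-scaled CPM, and log2 CPM used a prior count of 2. Fitted fold changes of genes at or near 0 in a region depend on the prior count, and levels are given for many of them, instead of or beside the fold change.

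Named genes followed a rule written before the data were examined. For each region against the others, these were the 10 highest and 5 lowest by fold change among genes that were called, had a mean of at least 5 CPM over the 30 libraries, an absolute log2 fold change of at least 1 and the same sign in both batches, leaving out predicted, clone, pseudogene and small RNA symbols. Also named were 8 genes of the astrocyte list and up to 4 genes of each described list with the smallest p, with list members that stand for the list's function whatever their p. Drd1a, Ppp1r1b, Slc17a7, Neurod6, Prox1, Gfap, Slc1a2, Slc1a3, Aldh1l1, Aqp4, Gja1, Slc6a11 and Apoe could be named whatever their p. For dorsal against ventral striatum the 6 highest and 6 lowest were taken, for the other pairs 2 each way, and for the batches 5 each way.

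From general knowledge 44 gene lists with 883 members were fixed before the data were examined, and 880 members were found, a few by an older symbol. Their cell type lists were astrocytes, neurons, striatal projection, cortical excitatory, hippocampal and amygdala or hypothalamic neurons, interneurons, oligodendrocytes and their precursors, microglia, endothelium, mural cells, fibroblasts, ependyma and choroid plexus, subventricular progenitors and blood. Function lists were pallial and subpallial transcription factors, glutamate and GABA handling, ion, water and gap junction genes, G-protein receptors and calcium, cholesterol synthesis, lipid transport and oxidation, glycolysis, the nuclear and the mitochondrially encoded respiratory chain, secreted synapse modifiers, extracellular matrix, Wnt, hedgehog, BMP and TGF-beta, Notch, thyroid and retinoid genes, reactive astrocyte genes (pan, A1 and A2), immediate early, heat shock, interferon and MHC, Alzheimer risk, antioxidant and metal, circadian and ribosomal protein genes. A list of sex-linked genes served as a check and was not tested, which left 43 lists, each with at least 4 tested members. Lists were tested with camera (limma 3.58.1; preset correlation 0.01, and an estimated correlation) and fry, adjusted over the 215 tests.

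Correlations used deviations from region and batch means or single batches, with permutation tests. Alternatives planned before the data were examined were DESeq2 size factors in edgeR, the DESeq2 1.42.0 test, limma-voom with quality weights, no low-count filter, a CPM of 1 in 6 libraries, no batch term, a block for the replicate number within each batch, each batch alone, the mean of the neuronal or of the oligodendrocyte genes as a covariate, each library left out, and the other gene set tests. Chosen after seeing the data were leaving out amygdala 1, amygdala 2 and dorsal striatum 4, summing the batch 2 hippocampus libraries, and thinning every library to the smallest total. Replicates were checked for libraries alike within sampling noise by chi-square over genes with at least 20 counts in a pair. The nearest, the batch 2 hippocampus libraries, differed by 2.69 to 4.13 times sampling noise and were kept apart. The labels do not say whether these 3 were separate immunoprecipitations, and as 1 preparation they would leave 4 hippocampus libraries and 408 lower genes in place of 816. The pipeline was tested on simulated data for hippocampus against the rest, where it called 24 of 67 genes changed 1.5-fold (35.8%), 47 of 67 changed 2-fold (70.1%) and 56 of 66 changed 4-fold (84.8%), and 8 of its 135 calls (5.93%) were false. The simulation drew genes independently of each other and changed them in hippocampus only. These shares therefore need not hold for the real libraries, where many genes vary together. Figures were drawn with Python 3.11.15, numpy 2.4.6 and matplotlib 3.10.9.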

Results

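RNA bound to astrocyte ribosomes was profiled in 5 regions of the wild-type mouse brain: prefrontal cortex, dorsal striatum, ventral striatum, amygdala and hippocampus. The mice carried a bacTRAP transgene, in which a tagged ribosomal protein is made under the control of the astrocyte gene Aldh1l1, so that an antibody to the tag pulls down ribosomes with the RNA they translate. There were 30 libraries, 6 per region, with 3 of each region in batch 1 and 3 in batch 2. Numbers 1 to 3 name the batch 1 libraries of a region and 4 to 6 those of batch 2. Total counts in batch 1 were 21119266, 19785531 and 19920939 in prefrontal cortex, 18771665, 17768455 and 19446754 in dorsal striatum. They were 22961665, 22918530 and 22540866 in ventral striatum, 20795287, 20789831 and 19892760 in amygdala, and 19416382, 21841296 and 18458631 in hippocampus. In batch 2 the totals were 7775864, 6881770 and 8157772 in prefrontal cortex, 7481436, 8224925 and 8465670 in dorsal striatum. The other batch 2 libraries had 6890513, 7432651 and 7316689 in ventral striatum, 7974370, 7250594 and 7669341 in amygdala, and 6936601, 7533148 and 8022998 in hippocampus. Fold changes are on the log2 scale with their SE, levels are CPM (counts scaled to a common library total) with the SD of 6 libraries, and a gene was called when its adjusted p in edgeR fell below 0.05. The CPM given for the other 4 regions is the plain mean of their means, which 1 high region can dominate. Its ratio to the region's level can therefore differ from the fold change, which is taken against their mean on the log scale. A gene high in some regions can for the same reason be called lower in the rest.

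With both batches together the main astrocyte transporters and channels were not called in any region against the mean of the other 4. Slc1a2 and Slc1a3, the glutamate transporters, differed from the mean of the other regions by −0.26 to 0.22 and by −0.46 to 0.25, and Aqp4, the water channel, by −0.27 to 0.31. Gja1, a gap junction protein, Slc6a11, a GABA transporter, and Apoe, a lipid carrier, were not called in any of the 5 comparisons either. Batch 2 alone differed: in dorsal striatum Slc1a2 (−0.69, adjusted p = 0.0131), Slc1a3 (−0.93, 0.00151), Aqp4 (−1.02, 0.00284), Gja1 (−0.90, 0.00271) and Slc6a11 (−0.91, 0.00287) were called lower. In ventral striatum it called Slc1a2 (0.75, 0.0126), Slc1a3 (0.76, 0.00836), Gja1 (0.75, 0.0123) and Slc6a11 (0.59, 0.0448) higher. The mean of all 95 astrocyte genes moved the same way in batch 2. It was lowest in dorsal striatum (7.85 log2 CPM) and highest in ventral striatum (8.71), so these calls are not particular to the transporters and channels. The spread between libraries was wide: Slc1a2 was at 4658 ± 1370 CPM in prefrontal cortex and at 5286 ± 3370 CPM in ventral striatum. Neuronal genes were present in every library, and the mean of 25 neuronal genes ran from 5.55 ± 1.09 log2 CPM in prefrontal cortex to 6.72 ± 1.22 in amygdala (SD, n = 6). The mean of 95 astrocyte genes ran from 7.83 ± 0.40 in dorsal striatum to 8.29 ± 0.45 in prefrontal cortex. In amygdala it was 7.14 in batch 1 and 8.6 in batch 2. The first principal component held 37.1% of the variance and followed the neuronal mean, with Pearson r −0.95 and Spearman rho −0.94 over the 15 libraries of batch 1. Over the 15 of batch 2 they were −0.90 and −0.92. Each permutation p was 1e-05, the smallest that these permutations can give, for the 2 relations tested, and r was −0.89 and −0.82 without the 2 libraries farthest from the median. The permutations mixed libraries of all regions, and the labels call those of a region technical replicates, so these p may be too small. The neuronal genes are also among those that define the component. Over all 30 libraries the component also followed batch (r 0.84), and the neuronal mean was lower in batch 2 in every region.

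**Figure D1:**
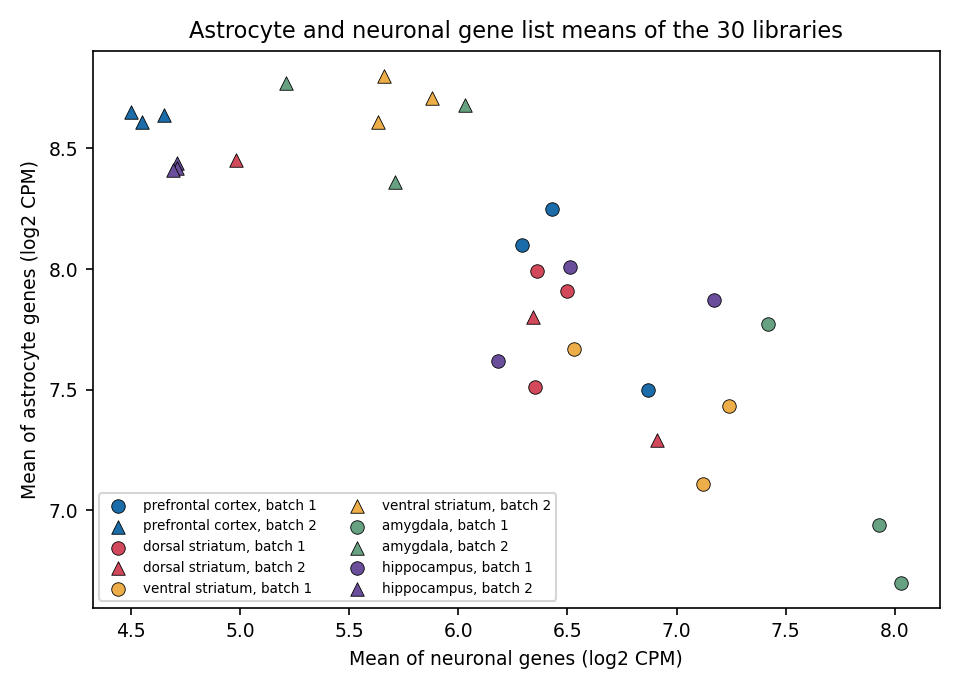
Mean log2 CPM of the fixed neuronal genes (x axis) against that of the fixed astrocyte genes (y axis) in each of the 30 libraries, coloured by region, with circles for batch 1 and triangles for batch 2. Batch 2 libraries lie mostly to the upper left, and amygdala 1 has the lowest astrocyte mean at 6.70.

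Of 15355 genes tested, 4828 (31.4%) differed among the 5 regions, and 3221 (21.0%) had a region difference that itself differed between the batches, 1321 of them in both sets. The count of 3221 became 988 without amygdala 1, amygdala 2 and dorsal striatum 4, 1701 with the batch 2 hippocampus libraries summed, 4992 with the DESeq2 test and 8621 with limma-voom. Of 43 gene lists fixed in advance and tested in 5 region comparisons, 94 of 215 tests were called by camera with its preset correlation, 18 of these also with an estimated correlation, and 63 by fry, 60 of them shared with camera. With region names shuffled within batches, camera with the preset correlation still called 33 to 93 tests (median 64). A list call by it alone is therefore weak evidence.

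**Figure D2:**
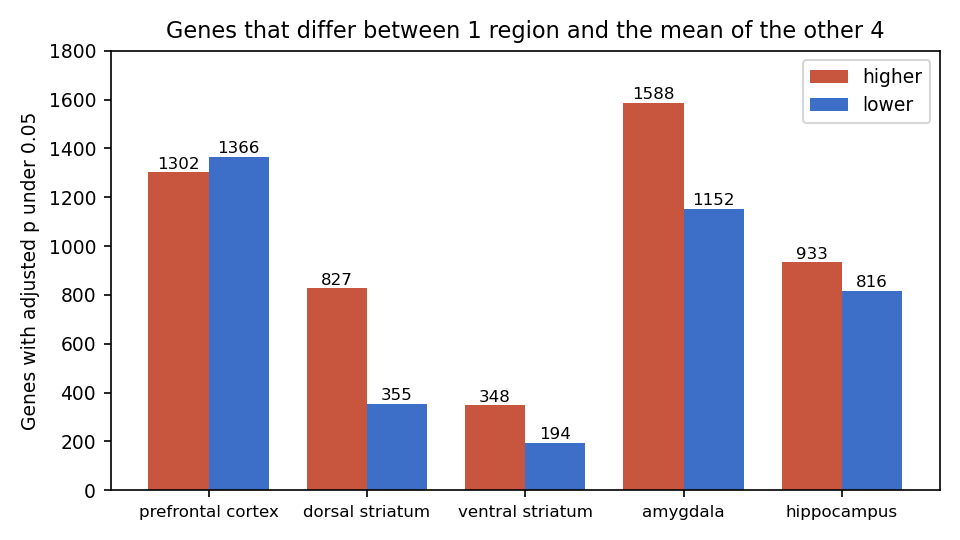
Number of genes (y axis) higher (red bars) and lower (blue bars) in each region (x axis) than in the mean of the other 4, called by edgeR over 15355 genes. Amygdala has 1588 higher genes and ventral striatum 348.

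The comparison of prefrontal cortex with the mean of the other 4 regions asked which astrocyte RNAs mark the cortex. Chrdl1, which encodes a secreted BMP antagonist that matures synapses, rose by 3.56 ± 0.25 (adjusted p = 6.35e-11) to 183 ± 79.9 CPM, against 19.8 CPM elsewhere. It was higher in 6 of 6 libraries, by 3.79 in batch 1 and 3.51 in batch 2. Car8, a carbonic anhydrase-like protein, rose by 2.40 ± 0.11 (adjusted p = 3.82e-15) to 267 ± 94.6 CPM from 55.9 CPM. The transcription factors Zic3, by 2.25 ± 0.25, and Tfcp2l1, by 1.91 ± 0.13, also rose, as did Cep128, a centriole protein, and Cdkn2c, a cell cycle inhibitor, by 2.00 ± 0.21. Glul, which makes glutamine from glutamate, rose by 1.17 ± 0.17 (adjusted p = 2.04e-05) to 7427 ± 493 CPM against 3398 CPM, but not with the oligodendrocyte covariate (0.50, adjusted p = 0.0898). Crym, a thyroid hormone binding protein, fell by 3.82 ± 0.52, at 25.2 CPM against 646 CPM, and Sparc, a secreted matrix protein, fell by 2.26 ± 0.31. Ttr, the choroid plexus thyroxine carrier, was at 1.70 ± 1.58 CPM against 1915 CPM, and Folr1, Kcne2 and Prlr, also choroid plexus genes, were at 0.0433, 0.0401 and 0.261 CPM against 13.4, 13.4 and 17.8 CPM. The call of Kcne2 ended in 5 of the 30 fits without a library: ventral striatum 2 (adjusted p = 0.0736) and 3 (0.136) and prefrontal cortex 4 (0.0502), 5 (0.0551) and 6 (0.0571). It also ended with limma-voom (0.109), in batch 1 (0.183) or 2 (1) alone, with the neuronal (0.0719) or oligodendrocyte covariate (0.128) and with thinned libraries (1), and that of Folr1 in batch 1 alone (0.144) and with the oligodendrocyte covariate (0.09). Gfap, the astrocyte filament, had −0.56 ± 0.25 (adjusted p = 0.119), but was called lower in batch 2 alone (−1.12, 0.000574), with the DESeq2 test (0.0498), limma-voom (0.00527), the neuronal (−0.79, 0.0337) or oligodendrocyte covariate (−1.33, 0.00136), and without amygdala 1 (0.0498) or the 3 libraries amygdala 1, amygdala 2 and dorsal striatum 4 (0.0076). Aldh1l1 rose by 0.79 ± 0.24 (adjusted p = 0.0211), by 1.39 in batch 1 and 0.22 in batch 2, and lost its call without prefrontal cortex 2 (0.64, adjusted p = 0.0878) or 3 (0.68, adjusted p = 0.0714), in batch 2 alone (0.28), and with the neuronal (0.65, adjusted p = 0.114) or oligodendrocyte covariate (0.12, adjusted p = 0.849).

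Cholesterol synthesis genes rose in prefrontal cortex, 11 of 22 with none down, and 14 rose and 1 fell adjusted over the list alone (camera up, adjusted p = 0.195 with an estimated correlation). Hmgcs1, the synthase of the pathway's start, rose by 1.06 ± 0.15 (1.37 in batch 1, 0.79 in batch 2), and Fdps and Insig1 by 0.77 ± 0.12 and 0.92 ± 0.14. Glycolysis, glycogen and lactate genes rose in 12 of 24, and in 16 adjusted over the list alone (adjusted p = 0.283 with an estimated correlation). Ldha, which makes lactate, rose by 0.64 ± 0.08 and the glycogen phosphorylase Pygm by 1.17 ± 0.20. Wnt pathway genes rose in 7 and fell in 1 of 18, or 9 and 1 adjusted over the list alone (adjusted p = 0.179 with an estimated correlation). Their Wnt targets Nkd1 and Axin2 rose by 1.43 ± 0.18 and 0.81 ± 0.15. Of 95 astrocyte genes 23 rose and 2 fell, 26 and 2 adjusted over the list alone, and camera's call upward had adjusted p = 0.681 with an estimated correlation. The pallial transcription factors split: Dmrta2 rose by 2.03 ± 0.24 and Emx2 by 0.97 ± 0.12 while Nr2f2 fell by 2.59 ± 0.21. Of 11 genes 6 rose and 1 fell, or 6 and 4 adjusted over the list alone (adjusted p = 0.383 with an estimated correlation). That list's median was 0.75 and its mean 0.16. Six3, a striatal transcription factor, fell by 3.65 ± 0.33.

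Genes of other cell types also differed in prefrontal cortex from the mean of the other 4 regions. Striatal projection neuron genes fell in 21 of 22, as they did adjusted over the list alone, and ependymal and choroid plexus genes in 13 of 15, also adjusted over the list alone. Both calls held with an estimated correlation (adjusted p = 0.0439 and 0.0218). The mean of the striatal projection neuron genes was 1.67 log2 CPM in prefrontal cortex and lower still in hippocampus (1.26). It was 5.91 in dorsal striatum, 5.24 in ventral striatum and 3.1 in amygdala, so the fall is set against a mean that holds the high striata. Oligodendrocyte genes fell in 15 of 16, and in 15 adjusted over the list alone (adjusted p = 0.179 with an estimated correlation). Plp1 fell by 1.91 ± 0.36 and Mbp, a myelin protein, was at 152 ± 132 CPM against 754 CPM. Neuronal genes fell in 12 and rose in 1 of 25, or 17 and 1 adjusted over the list alone (adjusted p = 0.594 with an estimated correlation). Cortical excitatory neuron genes rose in 5 of 17, 7 adjusted over the list alone (adjusted p = 0.447 with an estimated correlation), with Satb2 up by 2.44 ± 0.38 (2.96 in batch 1, and 1.69 in batch 2, where it was not called). Circadian clock genes rose in 3 of 16, as adjusted over the list alone (adjusted p = 0.447 with an estimated correlation), with Hlf, a clock-controlled factor, up by 0.57 ± 0.08. Nr1d2 (0.49) and Nr1d1 (0.54) also rose, but lost their calls without a batch term and with the neuronal or oligodendrocyte covariate. Nr1d2 was also not called in batch 1 alone, nor Nr1d1 in batch 2 alone. Nuclear respiratory chain genes rose in 2 of 49, as adjusted over the list alone, and camera's call upward had adjusted p = 0.812 with an estimated correlation. Reactive A1 genes fell in 2 of 11, as adjusted over the list alone (adjusted p = 0.454 with an estimated correlation). Camera also called microglia, endothelium, interneurons and 5 more lists downward, and none of these 8 held with an estimated correlation (adjusted p = 0.0628 to 0.661). In total 1302 genes were higher and 1366 lower, 2663 of these 2668 with the same sign in both batches. Of all genes, 1536 were called in batch 1 alone and 2131 in batch 2 alone. The higher count was 783 without prefrontal cortex 4 and 859 without prefrontal cortex 5. With the oligodendrocyte mean as a covariate 253 of the higher (19.4%) and 395 of the lower genes (28.9%) were still called, while Plp1 (−0.14, adjusted p = 0.649), Mbp (−0.16, adjusted p = 0.595), Axin2 (0.49, adjusted p = 0.109) and Pygm (0.41, adjusted p = 0.297) were no longer called.

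**Figure D3:**
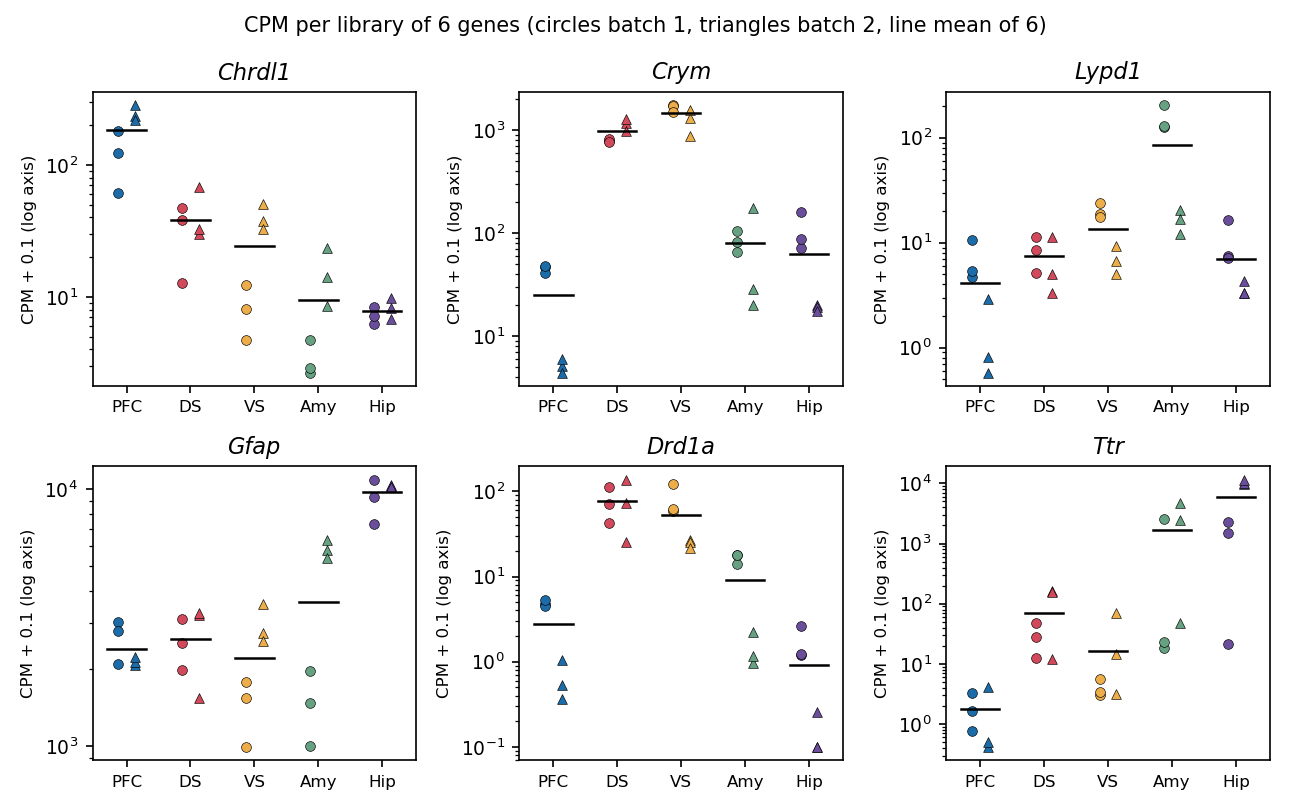
CPM plus 0.1, on a log axis, of Chrdl1, Crym, Lypd1, Gfap, Drd1a and Ttr in each library of the 5 regions, with circles for batch 1, triangles for batch 2 and a line at the mean of 6 libraries. Chrdl1 stands highest in prefrontal cortex (183 CPM) and Gfap in hippocampus (9709 CPM).

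Dorsal striatum against the mean of the other 4 regions asked for RNAs that mark the caudate. Drd1a, the dopamine D1 receptor, rose by 4.38 ± 0.35 (adjusted p = 3.37e-10), by 2.92 in batch 1 and 6.27 in batch 2. It was at 76.8 ± 42 CPM against a plain mean of 16.3 CPM in the other 4 regions, ventral striatum among them. Penk, the enkephalin precursor, reached 675 ± 388 CPM against 161 CPM, a rise of 4.35 ± 0.33, and Scn4b, a sodium channel subunit, rose by 4.65 ± 0.36. All 22 striatal projection neuron genes rose, also adjusted over the list alone, and the call held with an estimated correlation (adjusted p = 0.000162). Among them was Ppp1r1b, a dopamine signalling protein, up by 1.72 ± 0.22. Gpr6, Cd4 and Chat also stood among the 10 highest, and Cd4 was at 54.2 ± 34 CPM against 5.52 CPM. Crym rose by 3.38 ± 0.35 (adjusted p = 6.63e-08; 2.32 in batch 1, 4.44 in batch 2) to 979 ± 221 CPM, and the retinoid receptors Rxrg and Rarb by 2.60 ± 0.23 and 1.28 ± 0.20. Both receptors are also in the striatal projection neuron list. Thyroid and retinoid genes as a list rose in 5 and fell in 2 of 16, or 7 and 2 adjusted over the list alone, and were called with either correlation (estimated, adjusted p = 0.0144). With these shared members, that call is not independent of the call of the striatal projection neuron genes. Oligodendrocyte genes rose in 14 of 16, as they did adjusted over the list alone (adjusted p = 0.0439 with an estimated correlation), with Plp1 up by 2.06 ± 0.29 to 784 ± 470 CPM. Among 95 astrocyte genes 1 rose and 5 fell, the same adjusted over the list alone (adjusted p = 0.748 with an estimated correlation). Slc25a18, a mitochondrial glutamate carrier, fell by 1.36 ± 0.24 and Papss2, a sulfate donor enzyme, rose by 0.50 ± 0.12, while Gfap had −0.44 ± 0.24 (adjusted p = 0.354), but was called lower in batch 2 alone (−0.69, adjusted p = 0.00885). Kcnj16, a potassium channel subunit, fell by 1.16 ± 0.31 but not without dorsal striatum 6 (−1.01, adjusted p = 0.068), in batch 1 alone (−0.46, adjusted p = 0.313) or with the oligodendrocyte covariate (−0.45, adjusted p = 0.384).

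Fibroblast genes were low in dorsal striatum: 9 of 10 fell, 10 adjusted over the list alone (adjusted p = 0.0628 with an estimated correlation), with Dcn, a matrix proteoglycan, down by 2.63 ± 0.45 and Igf2 by 3.67 ± 0.63. Fmod was at 0.714 CPM against 32.1 CPM and Ptgds, a prostaglandin synthase of the meninges, at 86.0 ± 38 against 1914 CPM. The transcription factors of the subpallium split, with Isl1 up by 4.11 ± 0.36, Six3 by 2.38 ± 0.21 and Meis2 by 0.85 ± 0.14 against Zic3 down by 2.14 ± 0.34. Isl1 is also in the striatal projection neuron list. In all 7 of 17 rose and 4 fell, 8 and 7 adjusted over the list alone (adjusted p = 0.317 with an estimated correlation). Mitochondrially encoded genes rose in 6 of 10, 10 adjusted over the list alone (adjusted p = 0.483 with an estimated correlation), but only 4 of 10 had the same sign in both batches. Of these genes mt-Co1 rose by 0.04 in batch 1 and 2.85 in batch 2, and had −0.60 (adjusted p = 0.464) with the oligodendrocyte covariate. Interneuron genes rose in 6 and fell in 2 of 10, the same adjusted over the list alone (adjusted p = 0.263 with an estimated correlation). Subventricular progenitor genes rose in 2 of 9, 4 adjusted over the list alone (adjusted p = 0.447 with an estimated correlation). Ion, water and gap junction genes fell in 2 of 23, as adjusted over the list alone (adjusted p = 0.714 with an estimated correlation). Cholesterol synthesis genes fell in 1 of 22, and in 3 adjusted over the list alone (adjusted p = 0.447 with an estimated correlation). In total 827 genes were higher and 355 lower, 1128 of these 1182 with the same sign in both batches. Batch 1 alone called 545 higher and 597 lower, and batch 2 alone 1772 higher and 1329 lower. The lower count was 231 without dorsal striatum 6. The oligodendrocyte covariate ended the calls of Slc25a18 (−0.52, adjusted p = 0.0652), Meis2 (0.36, adjusted p = 0.143) and Ptgds (−2.62, adjusted p = 0.0706), as well as Plp1 (0.23, adjusted p = 0.347).

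Ventral striatum against the mean of the other 4 regions asked for RNAs that mark the accumbens area. Crym was highest, at 1461 ± 327 CPM against 287 CPM, a rise of 3.90 ± 0.34 (adjusted p = 9.58e-09) seen in 6 of 6 libraries, by 3.65 in batch 1 and 4.50 in batch 2. Rbp1, a retinol carrier, rose by 1.07 ± 0.16 to 331 ± 77.4 CPM, and thyroid and retinoid genes rose in 4 of 16, also 4 adjusted over the list alone, called with either correlation (estimated, adjusted p = 0.0191). Among those that rose were Rarb and Rxrg, which are also in the striatal projection neuron list and were not called in batch 2 alone. Hmgcs2, the ketone body synthase, rose by 0.98 ± 0.17 and the glycine transporter Slc6a9 by 1.00 ± 0.23, though not in batch 1 alone (0.58, adjusted p = 0.415), without a batch term (0.0886) or without ventral striatum 4 (0.0664). Eya1, a transcription cofactor, fell by 1.81 ± 0.20 to 9.45 ± 3.89 CPM from 41.8 CPM, and Thrsp, a lipogenic protein, fell by 0.86 ± 0.20. Pallial transcription factors fell in 8 of 11, 9 adjusted over the list alone (adjusted p = 0.000611 with an estimated correlation), with Nr2f1 down by 1.57 ± 0.20 and Dmrta2 by 2.49 ± 0.34. Subpallial ones rose in 9 and fell in 2 of 17, 10 and 2 adjusted over the list alone (adjusted p = 0.000738 with an estimated correlation), with Six3 up by 2.17 ± 0.22 and Isl1 by 3.47 ± 0.34. Isl1 also belongs to the striatal projection neuron list. Gfap fell by 0.87 ± 0.25 (adjusted p = 0.0468), a call that ended in 20 of the 30 fits without a library, at −0.74 (adjusted p = 0.162) without ventral striatum 3, and in 6 of the 14 other alternatives, such as the replicate block (−0.87, adjusted p = 0.0721) and the oligodendrocyte covariate (−0.44, adjusted p = 0.173). Ttr, at 16.5 ± 26.4 CPM, had adjusted p = 0.0279 and lost its call without ventral striatum 1 (adjusted p = 0.0636), 2 (0.0659), 3 (0.0793), 4 (0.0683) or 5 (0.0581), with limma-voom (0.3), without a batch term (0.144) and in batch 1 (0.108) or 2 (0.105) alone.

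Striatal projection neuron genes rose in 20 of 22 in ventral striatum, 22 adjusted over the list alone (adjusted p = 0.00026 with an estimated correlation). The substance P precursor Tac1 rose by 3.18 ± 0.27 to 76.0 ± 39 CPM and Penk by 2.88 ± 0.31. Amygdala and hypothalamic neuron genes rose in 6 of 13, 9 and 1 down adjusted over the list alone (adjusted p = 0.00128 with an estimated correlation). The neuropeptides Cartpt and Nts rose by 3.50 ± 0.31 and 3.33 ± 0.42. Cortical excitatory neuron genes fell in 6 of 17, 9 adjusted over the list alone (adjusted p = 0.0667 with an estimated correlation). Neurod6 fell by 3.13 ± 0.62 and the peptide Cck by 2.84 ± 0.48. Cholesterol synthesis genes fell in 3 of 22, 8 adjusted over the list alone (adjusted p = 0.438 with an estimated correlation), among them Fdps by 0.58 ± 0.13 (not called in batch 2 alone, adjusted p = 0.0679). Microglia genes rose in 1 of 17, 6 adjusted over the list alone (adjusted p = 0.347 with an estimated correlation). In total 348 genes were higher and 194 lower, 538 of these 542 with the same sign in both batches. Of all genes, 816 were called in batch 1 alone and 1029 in batch 2 alone. Without ventral striatum 3 the counts were 214 and 110, Neurod6 (−2.54, adjusted p = 0.0757) was not called in batch 2 alone, and Thrsp (−0.80, adjusted p = 0.277) was not called without a batch term.

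Amygdala against the mean of the other 4 regions asked for RNAs that mark that nucleus. Nr2f2, an orphan nuclear receptor, rose by 2.92 ± 0.15 (adjusted p = 2e-14) to 156 ± 31.1 CPM from 26.1 CPM, by 2.90 in batch 1 and 2.94 in batch 2, and its relative Nr2f1 by 1.07 ± 0.16. Lypd1, a modulator of nicotinic receptors, rose by 3.14 ± 0.28, by 3.86 in batch 1 and 2.07 in batch 2, to 84.6 ± 79.8 CPM, and Ngb, a neuronal globin, by 3.15 ± 0.35. Genes that fell included Tfcp2l1 by 2.33 ± 0.18, Chrdl1 by 2.10 ± 0.35, Thrsp by 1.23 ± 0.20 and Cep128 by 1.89 ± 0.21, Tfcp2l1 to 7.80 CPM from 42 CPM. Glul fell by 0.90 ± 0.20, but in batch 2 alone it (−0.33, adjusted p = 0.193), Gbe1 (−0.59, adjusted p = 0.144) and Cyp26b1 (1.67, adjusted p = 0.179) were not called. Of 95 astrocyte genes 3 rose and 18 fell, 5 and 23 adjusted over the list alone (adjusted p = 0.815 with an estimated correlation). Thyroid and retinoid genes fell in 9 and rose in 2 of 16, as adjusted over the list alone, and were called with either correlation (estimated, adjusted p = 0.043). Rbp1 fell by 1.23 ± 0.19 and Klf9, a thyroid hormone target, by 0.59 ± 0.10, while Cyp26b1, which degrades retinoic acid, reached 19.4 ± 20.1 CPM against 1.41 CPM. Glycolysis genes fell in 7 and rose in 1 of 24, 12 and 1 adjusted over the list alone (adjusted p = 0.462 with an estimated correlation), with Gbe1, the glycogen branching enzyme, down by 0.86 ± 0.17. Antioxidant and metal genes fell in 6 and rose in 2 of 24, 9 and 4 adjusted over the list alone (adjusted p = 0.53 with an estimated correlation), with Gclm, a glutathione synthesis subunit, down by 0.70 ± 0.13 and Txnrd1 by 0.59 ± 0.09. Gfap had −0.05 ± 0.24 (adjusted p = 0.904), with −1.08 in batch 1 and 0.68 in batch 2. The clock genes Hlf and Arntl fell by 0.64 ± 0.09 and 0.64 ± 0.15, Arntl without a call in batch 2 alone (adjusted p = 0.0738).

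Amygdala and hypothalamic neuron genes rose in 12 of 13 in amygdala, also adjusted over the list alone (adjusted p = 0.000476 with an estimated correlation), with Baiap3 up by 3.49 ± 0.41, Hap1 by 2.82 ± 0.30 and the neuropeptide Tac2 by 2.10 ± 0.23. Neuronal genes in general rose in 13 of 25, 15 adjusted over the list alone (adjusted p = 0.447 with an estimated correlation), with Gap43 up by 1.5 ± 0.27 (not called in batch 2 alone, adjusted p = 0.0803). Endothelial genes rose in 12 of 14, 14 adjusted over the list alone (adjusted p = 0.11 with an estimated correlation), and microglia genes in 11 of 17, 14 adjusted over the list alone (0.383). The lipid transfer protein Pltp rose by 1.67 ± 0.22 and the complement gene C1qa by 1.52 ± 0.29 to 2.00 CPM (2.13 in batch 1, and 0.62 in batch 2, where it was not called). The call of C1qa also ended with the neuronal covariate. Ependymal and choroid plexus genes rose in 8 of 15, 10 adjusted over the list alone (adjusted p = 0.205 with an estimated correlation). Ttr was at 2538, 18.6, 23.3, 47.5, 4803 and 2491 CPM in amygdala 1 to 6. Cldn2, a choroid plexus claudin, rose by 3.33 ± 0.67 but not without amygdala 1 (1.64, adjusted p = 0.162), with limma-voom (0.438), with the neuronal covariate (0.106) or without the 3 libraries amygdala 1, amygdala 2 and dorsal striatum 4 (0.0972). Ttr was not called with limma-voom (0.0534). Oligodendrocyte precursor genes rose in 3 of 7, as adjusted over the list alone (adjusted p = 0.448 with an estimated correlation), and mitochondrially encoded genes in 10 of 10, as adjusted over the list alone (0.553), but only 5 of 10 with the same sign in both batches. Ribosomal protein genes were called downward by camera with 1 up and 1 down of 46, 0 adjusted over the list alone (adjusted p = 0.879 with an estimated correlation). In total 1588 genes were higher and 1152 lower, 2659 of these 2740 with the same sign in both batches. Of all genes, 4949 were called in batch 1 alone and 852 in batch 2 alone. The counts were 750 and 580 without amygdala 1 and 1049 and 678 without amygdala 2. Of the higher genes 414 (26.1%) were still called with the neuronal mean as a covariate.

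Hippocampus against the mean of the other 4 regions asked for RNAs that mark hippocampal astrocytes. Gfap rose by 1.92 ± 0.21 (adjusted p = 1.86e-07) to 9709 ± 1270 CPM against 2706 CPM, in 6 of 6 libraries, by 2.23 in batch 1 and 1.71 in batch 2. Thrsp rose by 1.41 ± 0.17 and Fezf2, a forebrain transcription factor, by 1.72 ± 0.15, while Chrdl1 fell by 1.94 ± 0.35. Pan-reactive genes rose in 7 of 9, as adjusted over the list alone (adjusted p = 0.0628 with an estimated correlation). The protease inhibitor Serpina3n rose by 0.93 ± 0.18 and Aspg by 1.21 ± 0.25. Vim, a filament protein, rose by 0.95 ± 0.24, though not without hippocampus 1 (0.79, adjusted p = 0.0591) or in batch 2 alone (0.49, adjusted p = 0.182). Reactive A2 genes rose in 3 of 8, 5 adjusted over the list alone (adjusted p = 0.0144 with an estimated correlation), and S100a10 was up by 1.32 ± 0.17 to 117 ± 28.4 CPM from 47.8 CPM. Cd14 and Ptgs2 also rose, by 1.30 and 1.95, but were not called in batch 2 alone. Pallial transcription factors rose in 7 of 11, 9 and 1 down adjusted over the list alone (adjusted p = 0.00348 with an estimated correlation). Emx1 was at 8.92 ± 2.08 CPM against 0.968 CPM and Nr2f1 up by 1.28 ± 0.16. Subpallial ones fell in 11 and rose in 3 of 17, 11 and 4 adjusted over the list alone (adjusted p = 0.00936 with an estimated correlation). Meis1 fell by 1.74 ± 0.18 and Meis2 by 1.29 ± 0.17. Interferon and MHC genes rose in 5 of 18, 11 adjusted over the list alone (adjusted p = 0.447 with an estimated correlation), with the immunoproteasome subunit Psmb9 up by 1.2 ± 0.20. Isg15, Ifit1 and Stat2 also rose, but their calls ended in 4, 7 and 8 of the 14 other alternatives. They also ended in 4, 9 and 25 of the 30 fits without a library. Notch genes fell in 5 of 13, as adjusted over the list alone (adjusted p = 0.447 with an estimated correlation), with Hes5 down by 0.91 ± 0.18, but not called in batch 1 alone (−0.64, adjusted p = 0.059). Genes of G-protein receptors and calcium fell in 5 and rose in 1 of 26, as adjusted over the list alone (adjusted p = 0.447 with an estimated correlation). Glutamate and GABA handling genes fell in 5 of 25, 6 adjusted over the list alone (adjusted p = 0.493 with an estimated correlation), and the GABA-B subunit Gabbr2 fell by 1.49 ± 0.21. Gpc4, a glypican that recruits glutamate receptors, rose by 1.36 ± 0.22 and Crym fell by 2.16 ± 0.46.

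Choroid plexus RNA was most abundant in hippocampus, where Ttr was at 5921 ± 5170 CPM against 435 CPM and rose by 6.70 ± 0.70. Single libraries had 21.7 CPM in hippocampus 2 and 11550 CPM in hippocampus 6. Sostdc1 and Kl, also choroid plexus genes, rose by 5.53 ± 0.52 and 3.58 ± 0.53. In all 13 of 15 ependymal and choroid plexus genes rose, as adjusted over the list alone (adjusted p = 0.00936 with an estimated correlation). Hippocampal neuron genes rose in 7 and fell in 1 of 11, as adjusted over the list alone (adjusted p = 0.00097 with an estimated correlation). Prox1, a dentate granule cell factor, rose by 2.10 ± 0.19 to 31.8 ± 19.6 CPM and Dsp was at 17.1 ± 20.6 CPM against 0.266 CPM. Striatal projection neuron genes fell in 18 of 22, 21 adjusted over the list alone (adjusted p = 0.00936 with an estimated correlation). As in prefrontal cortex, this fall is set against a mean that holds both striata, where these genes were high. Penk was at 5.66 ± 4.64 CPM against 328 CPM, and Gpr6, Cd4 and Chat were at 0.0401, 0.118 and 0.0588 CPM. Mitochondrially encoded genes fell in 10 of 10, as adjusted over the list alone (adjusted p = 0.383 with an estimated correlation), with mt-Nd1 down by 2.68 ± 0.62. Fibroblast genes rose in 5 of 10, 8 adjusted over the list alone (adjusted p = 0.347 with an estimated correlation), with Dcn up by 1.60 ± 0.33. Microglia genes fell in 7 of 17, 15 adjusted over the list alone (adjusted p = 0.321 with an estimated correlation). Blood genes fell in 1 of 5, 3 adjusted over the list alone (adjusted p = 0.528 with an estimated correlation). Cortical excitatory neuron genes rose in 5 and fell in 3 of 17, as adjusted over the list alone (adjusted p = 0.594 with an estimated correlation), with Neurod6 up by 2.58 ± 0.41. In total 933 genes were higher and 816 lower, 1742 of these 1749 with the same sign in both batches. Of all genes, 1528 were called in batch 1 alone and 1252 in batch 2 alone. The counts were 601 and 512 without hippocampus 1, the lower count was 541 without hippocampus 2, and they were 639 and 408 with the 3 batch 2 hippocampus libraries summed. In batch 2 alone Dcn (1.01, adjusted p = 0.175), Cd4 (0.0515) and Gpr6 (1) were not called.

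**Figure D4:**
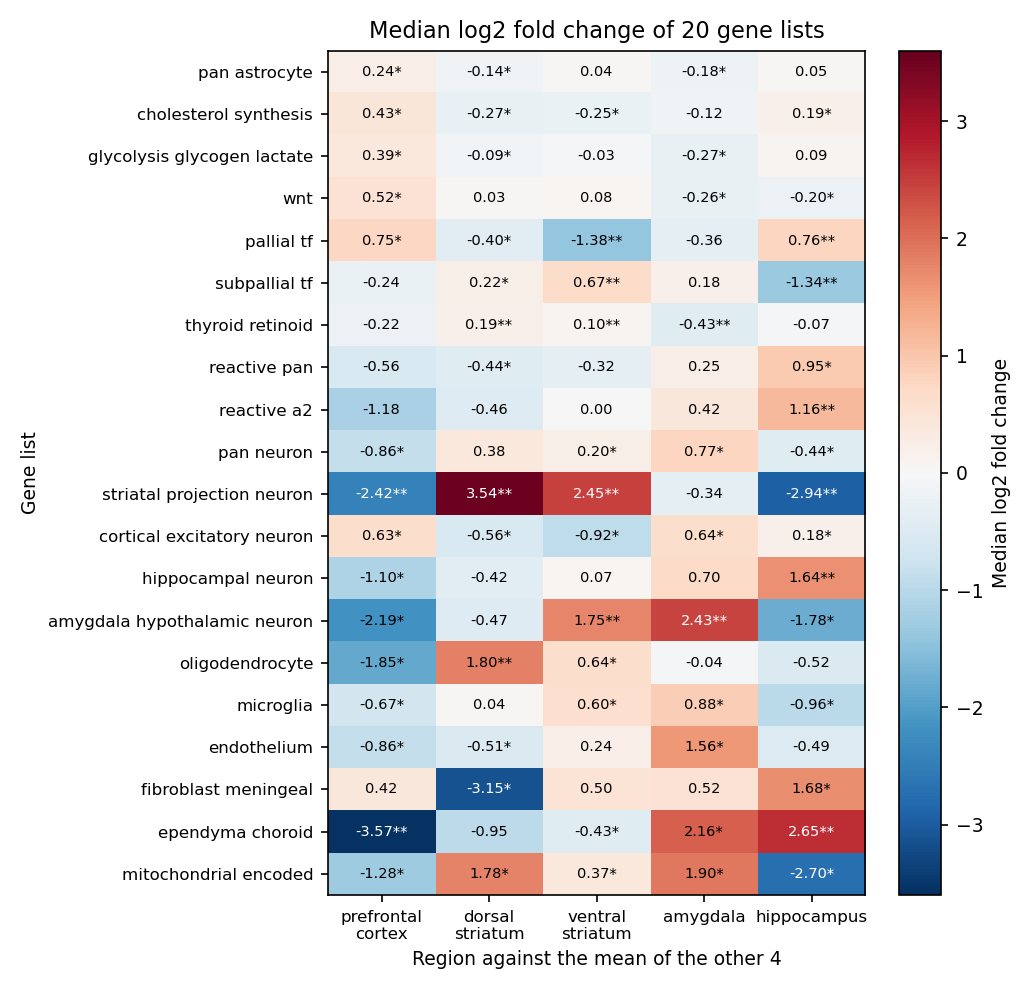
Median log2 fold change of 20 fixed gene lists in each region against the mean of the other 4, on a colour scale, with 1 star where camera with its preset correlation called the list and a second star where the estimated correlation did too. Striatal projection neuron genes have medians of 3.54 in dorsal striatum, 2.45 in ventral striatum and −2.94 in hippocampus.

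Camera called 9 lists in no region. Alzheimer risk genes had 6 up and 1 down of 26 in amygdala, the same adjusted over the list alone, and 3 up and 6 down in prefrontal cortex, where 4 rose and 6 fell adjusted over the list alone. BMP and TGF-beta genes had 2 up and 1 down of 20 in prefrontal cortex, where Bmp7 rose by 0.92 (not called in batch 2 alone, 0.114, or with the neuronal, 0.103, or oligodendrocyte covariate, 0.822), and 0 up and 3 down in amygdala, both as adjusted over the list alone. Extracellular matrix genes fell in 6 and rose in 2 of 27 in prefrontal cortex, and synapse-modifying secreted proteins rose in 2 and fell in 5 of 21, both as adjusted over the list alone. Hedgehog genes rose in 3 and fell in 2 of 11 there, as adjusted over the list alone, with Gli3, a hedgehog pathway repressor, up by 0.93 ± 0.12. Lipid transport and oxidation genes rose in 5 and fell in 3 of 25 in prefrontal cortex, 6 and 3 adjusted over the list alone. Immediate early genes rose in 2 and fell in 1 of 19 in dorsal striatum, 4 and 1 adjusted over the list alone, with Egr1 up by 1.89 ± 0.34 (not called in batch 1 alone, 0.375, without a batch term, 0.136, or with the oligodendrocyte covariate, 0.978). Heat shock genes rose in 2 of 11 and mural genes in 2 of 8 in amygdala, or 2 of 11 and 4 of 8 adjusted over the list alone, where 1 mural gene fell.

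Dorsal against ventral striatum asked how astrocytes of these neighbouring regions differ. It called 30 genes higher in dorsal and 36 higher in ventral, all 66 with the same sign in both batches. Zic3 was lower in dorsal striatum, at 1.59 ± 1.26 against 9.82 ± 3.6 CPM, by −2.56 ± 0.39 (adjusted p = 0.00108, n = 6 and 6, edgeR). Higher in dorsal striatum were Scel, a cornified envelope protein, by 3.03 ± 0.48 (adjusted p = 0.00138), at 19.0 ± 2.84 against 2.41 ± 1.28 CPM, and Coch, a secreted matrix protein, by 2.79 ± 0.39, at 31.3 ± 15.4 against 4.69 ± 2.63 CPM. Cnr1, the cannabinoid receptor, was at 128 ± 57.3 against 32.0 ± 15.2 CPM and Nrgn, a calmodulin-binding neuronal protein, rose by 2.45 ± 0.48. Lef1, a Wnt effector, rose by 2.11 ± 0.45 and lost its call without ventral striatum 1 (2.03, adjusted p = 0.057) or dorsal striatum 5 (1.98, adjusted p = 0.0541). Col1a2, Fmod, Igf2, Islr and Vtn, genes of fibroblasts and vessel walls, were lower in dorsal striatum, Col1a2 by −2.50 ± 0.46. Without ventral striatum 4, which held 165 CPM of Fmod, Fmod had −3.03 (adjusted p = 0.165), Igf2 −1.69 (0.168), Islr −1.92 (0.051) and Vtn −1.21 (0.175). The replicate block ended the calls of Fmod (−4.20, adjusted p = 0.103), Igf2 (−2.76, adjusted p = 0.0776) and Vtn (−1.90, adjusted p = 0.0671), and none of the 5 genes, nor Nrgn (0.95, adjusted p = 0.258) or Lef1 (2.00, adjusted p = 0.0944), was called in batch 1 alone. The calls of Fmod, Igf2, Islr and Vtn ended in 10, 5, 3 and 19 of the 30 fits without a library, and the count of 66 fell to 39 without dorsal striatum 6. Each batch alone gave 108 and 1544 genes, and without a batch term Nrgn (2.17, adjusted p = 0.0859), Cnr1 (1.99, adjusted p = 0.209), Col1a2 (−2.83, adjusted p = 0.0676), Lef1 (2.12, adjusted p = 0.0737), Igf2 (0.0853), Islr (0.151) and Vtn (0.0634) were not called. Limma-voom did not call Nrgn (0.0556), Fmod (0.291), Igf2 (0.194) or Vtn (0.117).

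The remaining 9 pairs asked which genes separate each region from each other. Prefrontal cortex against amygdala had 1863 genes higher and 2207 lower, with Chrdl1 higher by 4.53 ± 0.43. It was also higher in prefrontal cortex than in ventral striatum, by 3.16 ± 0.40, with 805 genes higher and 1044 lower in that pair, and than in hippocampus, by 4.40 ± 0.43, with 500 and 745. Crym was at 25.2 CPM in prefrontal cortex against 1461 CPM in ventral striatum. Prefrontal cortex against dorsal striatum had 724 genes higher and 1308 lower. Fmod was up by 4.90, at 16.6 against 0.714 CPM, and Sh3rf2, a signalling scaffold, was at 0.252 against 23.4 CPM. Dorsal striatum against amygdala had 781 higher and 830 lower, with Tph2, the serotonin synthesis enzyme, at 15.8 ± 3.88 against 0.552 CPM. Dorsal striatum against hippocampus had 1000 higher and 706 lower, with Sostdc1 lower by −6.16 ± 0.88, at 0.727 against 66.6 CPM. Ventral striatum against amygdala had 327 higher and 337 lower, with Crym up by 4.16 ± 0.56, and against hippocampus 787 and 791, with Ttr at −8.45 ± 1.33. Amygdala against hippocampus had 1239 higher and 964 lower, with Cxcl5, a chemokine, at 1.03 against 18.1 ± 6.16 CPM. Without amygdala 1 the pair with ventral striatum had 431 genes and that with hippocampus 1384, and without hippocampus 1 the latter had 1267. With the oligodendrocyte covariate Fmod had 2.76 (adjusted p = 0.242) in prefrontal cortex against dorsal striatum.

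Between the batches 4816 genes were higher and 4826 lower in batch 2 (9642, 62.8%). Apoe was at 9787 CPM in batch 2 against 1990 CPM in batch 1, a difference of 2.20 ± 0.29, and Gpr37l1, an astrocyte receptor, rose by 2.20 ± 0.17. Mamdc2 by 2.74 ± 0.26, Sod3, an extracellular superoxide dismutase, by 2.23 ± 0.25 and Ptgds by 2.24 ± 0.67 were also higher. Among the genes lower in batch 2, Dync1h1, the dynein heavy chain, was at 57.1 against 448 CPM, and Tenm1, Ppp1r9a, Ryr2 and Cnksr2 fell by 3.25 ± 0.28, 3.14 ± 0.29, 3.09 ± 0.33 and 3.02 ± 0.30. The neuronal mean was also lower in batch 2 in every region, from 6.4 to 6.08 log2 CPM in dorsal striatum and from 7.8 to 5.65 in amygdala. The batch differences were not separated from this shift.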

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

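All tests of explanations below were chosen after the patterns were seen, while the comparisons with other splits of the samples were planned before. Of 85 checks for a library far from the other 5 of its region, 5 exceeded the limit, where chance gives about 4.2 (1 in 20). Dorsal striatum 5 had a low neuronal mean, 4.98 log2 CPM against 6.34 to 6.91 in the other 5 (gap over range 0.703), and hippocampus 2 was low for Ttr (0.674), Kcne2 (0.63), Sostdc1 (0.637) and Cldn2 (0.649), which move together. Of 75 genes named as highest or lowest in a region, 12 had a region difference that itself differed between the batches. In dorsal striatum these included Gpr6 (adjusted p = 0.0109), Syndig1l (0.0481), Scn4b (0.00764), Drd1a (0.001), Penk (0.00186), Sh3rf2 (0.0159) and Ptgds (0.0211), by edgeR and each larger in batch 2. In amygdala they were Cyp26b1 (0.0187), Lypd1 (0.0211) and Tfcp2l1 (0.00725), larger in batch 1, and in hippocampus Calml4 (0.0223), with 2.66 in batch 1 and 7.02 in batch 2.

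Striatal projection neuron genes were high in both striata in an astrocyte preparation. Within regions and batches, over 12 striatal libraries, their mean rose with the mean of 25 neuronal genes (r 0.89, p = 0.015, adjusted 0.038 over 5 relations; rho 0.78, p = 0.017; r 0.71 in batch 1 and 0.94 in batch 2; 1296 exact permutations; r 0.59 without the 2 farthest libraries), with slope 1.10 (0.60 to 1.60), so RNA of striatal neurons in the immunoprecipitate may be their source. Expression by astrocytes stays open: the slope on the astrocyte mean was −1.13 (−2.48 to 0.22; r −0.60, p = 0.28, adjusted 0.28; rho −0.29, p = 0.51; r 0.22 in batch 1, −0.89 in batch 2, and 0.27 without the 2 farthest). Crym did not follow the neuronal mean, with slope −0.17 (−0.55 to 0.21; r −0.37, p = 0.2, adjusted 0.25; rho −0.66, p = 0.048; r −0.58 in batch 1, −0.35 in batch 2, and −0.53 without the 2 farthest). This argues against RNA of striatal neurons as its source only in so far as single genes of such neurons follow that mean. Over all 30 libraries Drd1a (slope 0.98) and Penk (1.02) followed it, but Gpr6 (0.20) did so weakly. Striatal astrocytes with high Crym remain a hypothesis, and a difference between regions in how the tissue was taken was not tested.

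Choroid plexus genes were high in hippocampus and amygdala and varied widely between libraries of a region. Over these 12 libraries, within regions and batches, 7 choroid plexus genes followed Ttr (r 0.99, p = 0.0077, adjusted 0.038; rho 0.96, p = 0.013; r 0.99 in batch 1, 1 in batch 2, and 0.99 without the 2 farthest), while 5 ependymal genes did not (r −0.30). Choroid plexus tissue in the dissected pieces is a candidate source. For neuronal RNA as the source the values cannot decide. The SD of the 8 choroid genes was 6.01 times that of the neuronal mean (2.86 to 12.66). Their wide variation was known when this ratio was chosen, so the ratio restates the pattern. Their slope on the neuronal mean was 3.26 (−1.26 to 7.78), and their r with it was 0.54 (p = 0.17, adjusted 0.25; rho 0.59, p = 0.16; r 0.33 in batch 1, 0.97 in batch 2, and 0.40 without the 2 farthest). A biological difference between these regions in such cells was not tested.

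The 10 genes highest in prefrontal cortex, Chrdl1, Car8, Zic3, Cep128, Nupr1, Cdkn2c, Lef1, Tfcp2l1, Vip and Car3, had a median of 2.03 (1.76 to 3.56). With the neuronal mean as a covariate 10 of the 10 were called (median 1.87), which argues against less neuronal RNA as the whole cause. With the oligodendrocyte mean as a covariate 7 of the 10 were called, and the median of all 10 was 1.54 (0.72 to 2.98). Nupr1 (2.06 ± 0.27 before, 0.72 after, adjusted p = 0.145), Car3 (1.76 ± 0.34 before, 0.72 after, adjusted p = 0.336) and Vip (1.90 ± 0.32 before, 1.52 after, adjusted p = 0.0572) were not. Less oligodendrocyte RNA would raise all other RNA alike. The 10 genes stood 1.80 (median; 1.53 to 3.33) above the median of 94 other astrocyte genes, 0.23 with SD 0.48. They were picked as the highest, however, so they stand above that median whatever the cause. This test, chosen after the covariate had ended those 3 calls, therefore cannot decide. Less oligodendrocyte RNA stays open as a cause. A difference of cortical astrocytes stays open.

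The counts were set against splits of the libraries, 100 per comparison. Region names were shuffled within batches, and for the batch difference and the interaction batch names were shuffled within regions. The labels call the libraries of a region technical replicates and the splits did not keep libraries of the same number together, so chance as the source of the counts can be excluded only against the spread between these libraries. The 4828 genes that differ among regions compare with at most 15 in any other split. Each region against the rest gave 2668 genes against a highest other of 557 (prefrontal cortex), 1182 against 137 (dorsal striatum), 542 against 188 (ventral striatum), 2740 against 137 (amygdala) and 1749 against 136 (hippocampus). Pairs gave 2032 against 6 (prefrontal cortex and dorsal striatum), 1849 against 9 (with ventral striatum), 4070 against 24 (with amygdala), 1245 against 344 (with hippocampus), 1611 against 79 (dorsal striatum and amygdala), 1706 against 172 (with hippocampus), 664 against 330 (ventral striatum and amygdala), 1578 against 24 (with hippocampus) and 2203 against 0 (amygdala and hippocampus). For dorsal against ventral striatum, 3 of the 100 splits, the real one included, gave at least 66 genes. That share is low but does not by itself exclude chance, as other groupings went above the real count. The other 2 gave 399 and 713, several times the real count, which points to a structure of the samples. The first of them sets dorsal libraries of batch 1 and ventral libraries of batch 2 against the reverse, and the real split gave 108 genes in batch 1 and 1544 in batch 2. For the interaction, 4 of 100, the real one included, gave at least 3221 genes. The other 3 gave up to 5430 and follow batch in part, which points to a structure of the samples: each keeps most batch names in 2 regions and swaps most in 3. With batch names shuffled, the batch difference entered the spread between libraries in most splits. These splits therefore cannot exclude chance for the interaction. The batch difference gave 9642 against 7094. The fixed lists gave 94 calls against a highest other of 93 and a median of 64. Camera with its preset correlation thus called many lists under shuffled region names. A count just above the highest other split does not exclude chance as the source of these calls.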

How the results depend on the processing

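Alternatives were planned before the data were examined, except leaving out amygdala 1, amygdala 2 and dorsal striatum 4, summing the batch 2 hippocampus libraries and thinning to the smallest total, which were chosen after seeing the data. A count is given below where it moved by more than 1.5 times, and unless said the cause was not tested. DESeq2 size factors, no low-count filter, the filter of CPM 1 in 6 libraries and thinning moved none of the 24 counts.

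Without a batch term 2528 genes differed among regions. Higher and lower counts were 693 and 623 in prefrontal cortex, 323 and 161 in dorsal striatum, 188 and 68 in ventral striatum, 908 and 546 in amygdala and 563 and 375 in hippocampus. Pairs had 928 (prefrontal cortex and dorsal striatum), 858 (with ventral striatum), 2123 (with amygdala), 697 (with hippocampus), 18 (dorsal and ventral striatum), 785 (dorsal striatum and amygdala), 899 (with hippocampus), 246 (ventral striatum and amygdala), 850 (with hippocampus) and 973 (amygdala and hippocampus). By construction the batch difference then adds to the residual spread.

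Limma-voom gave 2531 and 2331 in prefrontal cortex, 1250 and 1246 in dorsal striatum, 547 higher in ventral striatum, and 1862 and 1571 in hippocampus. Its pairs had 3738 and 2969 (prefrontal cortex and dorsal or ventral striatum), 3448 (prefrontal cortex and hippocampus), 293 (dorsal and ventral striatum), 2961 and 3182 (dorsal striatum and amygdala or hippocampus) and 2519 (ventral striatum and hippocampus), and its interaction had 8621 genes. The DESeq2 test gave 546 lower in dorsal striatum, 356 lower in ventral striatum, 217 between the striata, 1015 between ventral striatum and amygdala, and 4992 for the interaction.

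Batch 1 only gave 765 and 771 in prefrontal cortex, 545 and 597 in dorsal striatum, 322 lower in ventral striatum, and 2899 and 2050 in amygdala. Its pairs had 1076 (prefrontal cortex and dorsal striatum), 578 (prefrontal cortex and hippocampus), 108 (the striata), 4015 (dorsal striatum and amygdala), 1125 (ventral striatum and amygdala) and 3641 (amygdala and hippocampus). Batch 2 only gave 1772 and 1329 in dorsal striatum, 718 and 311 in ventral striatum and 527 and 325 in amygdala, with 3178 (prefrontal cortex and dorsal striatum), 1797 (prefrontal cortex and amygdala), 1544 (the striata), 347 (ventral striatum and amygdala) and 620 (amygdala and hippocampus). In batch 2 only, Gfap in amygdala (0.68, adjusted p = 0.0156, from −0.05) and Aldh1l1 in ventral striatum (0.50, adjusted p = 0.0269, from −0.05) turned upward.

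With the neuronal covariate there were 617 lower in dorsal striatum, 709 and 462 in ventral striatum, 658 and 760 in amygdala, 1782 between prefrontal cortex and amygdala, 1876 between prefrontal cortex and hippocampus, 261 between the striata and 1133 between amygdala and hippocampus. The oligodendrocyte covariate gave 1609 and 1434 in dorsal striatum, 784 and 599 in ventral striatum and 2756 and 2618 in amygdala. Its pairs had 2020 (prefrontal cortex and amygdala), 2065 (prefrontal cortex and hippocampus), 327 (the striata), 5361 (dorsal striatum and amygdala), 4017 (ventral striatum and amygdala) and 3362 (amygdala and hippocampus). Of the genes higher in dorsal striatum 95.8% remained with the neuronal covariate and 31.9% with the oligodendrocyte covariate, which by construction removes differences that follow myelin genes. In prefrontal cortex 47.5% and 19.4% remained, and Nr1d1 there turned from 0.54 to −0.08 (adjusted p = 0.834) with the oligodendrocyte covariate, and mt-Co1 in dorsal striatum from 1.68 to −0.60 (adjusted p = 0.464).

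The share of higher genes moved by more than 10 points in 17 of these fits. From 70.0% in dorsal striatum it went to 47.7% in batch 1, 57.1% in batch 2, 50.1% with limma-voom and 52.9% with the oligodendrocyte covariate. The DESeq2 test took prefrontal cortex from 48.8% to 38.3% and ventral striatum from 64.2% to 54.0%, and the neuronal covariate took amygdala from 58.0% to 46.4%. Prefrontal cortex against dorsal striatum went from 35.6% to 50.5% (limma-voom), 47.8% (batch 2) and 47.4% (oligodendrocyte covariate), and against hippocampus from 40.2% to 50.8% (oligodendrocyte covariate). The striata went from 45.5% to 33.3% (no batch term) and 55.6% (neuronal covariate), dorsal striatum against hippocampus from 58.6% to 47.6% (limma-voom) and 46.0% (batch 1), and ventral striatum against amygdala from 49.2% to 35.3% (batch 1) and 62.6% (neuronal covariate).

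Without amygdala 1, amygdala 2 and dorsal striatum 4 there were 573 and 361 in ventral striatum, 528 and 372 in amygdala, 2328 (prefrontal cortex and amygdala), 135 (the striata), 1035 (dorsal striatum and amygdala), 405 (ventral striatum and amygdala), 1030 (amygdala and hippocampus) and 988 for the interaction. Summing the batch 2 hippocampus libraries, which leaves 4 hippocampus libraries, gave 408 lower in hippocampus, 774 between prefrontal cortex and hippocampus and 1701 for the interaction. Camera with an estimated correlation kept 18 of 94 list calls.

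Leaving out each library in turn gave 783 to 1353 higher in prefrontal cortex (783 without prefrontal cortex 4, 859 without prefrontal cortex 5) and 231 to 366 lower in dorsal striatum (231 without dorsal striatum 6). Ventral striatum had 214 to 486 higher and 110 to 261 lower, both lowest without ventral striatum 3. Amygdala had 750 to 2148 higher and 580 to 1546 lower, lowest without amygdala 1, with 1049 and 678 without amygdala 2. Hippocampus had 601 to 1010 higher and 512 to 948 lower, lowest without hippocampus 1, with 541 lower without hippocampus 2. The striata had 39 to 87 (39 without dorsal striatum 6), ventral striatum and amygdala 431 to 930 (431 without amygdala 1), and amygdala and hippocampus 1267 to 2615 (1267 without hippocampus 1, 1384 without amygdala 1).

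The replicate block, which treats libraries of the same number within a batch as a set, moved no count: 4526 genes differed among regions, 66 became 63 between the striata, and list calls were 97. It ended 5 named calls: Gfap in ventral striatum (−0.87, adjusted p = 0.0721), Hmgcs2 in dorsal striatum (0.58, 0.0589), and Fmod (−4.20, 0.103), Igf2 (−2.76, 0.0776) and Vtn (−1.90, 0.0671) between the striata. The labels link libraries of different regions only by that number. After region means were removed, pairs of the same number in batch 1 had a median correlation across genes of 0.16 (−0.16 to 0.58), with 19 of 30 pairs above 0.1 and 12 of 15 libraries nearest to their own number, and in batch 2 a median of 0, with 1 of 15.

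Of 310 calls of genes named in the text or by the rule, 309 remained with DESeq2 size factors, 309 without a filter, 309 with the CPM filter and 293 with limma-voom, and 308 of 308 with the DESeq2 test. Of the 300 that do not compare the batches, 272 remained without a batch term, 295 with the replicate block, 272 in batch 1 only, 240 in batch 2 only, 274 with the neuronal and 253 with the oligodendrocyte covariate. Leaving out each library kept 278 of 300 in every fit. At least 1 of the 14 other alternatives ended 34 of 59 named calls in prefrontal cortex, 15 of 41 in dorsal striatum, 12 of 36 in ventral striatum, 30 of 55 in amygdala, 18 of 61 in hippocampus and 9 of 12 between the striata. On simulated data, with genes drawn independently of each other, 35.8% of 1.5-fold changes were called. With every library thinned to the smallest total 304 of 309 named calls remained.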

Other observations

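The test of libraries without amygdala 1, amygdala 2 and dorsal striatum 4 was chosen after the data were seen. Hmgcs2, which makes ketone bodies, was lower in prefrontal cortex and in hippocampus, by −0.91 ± 0.20 in each, and higher in dorsal striatum, by 0.58 ± 0.18. In batch 1 alone none of these was called (adjusted p = 0.139, 0.112 and 0.131), and the last call also ended with the replicate block (0.0589), without a batch term and in 6 of the 30 fits without a library. Summing the batch 2 hippocampus libraries ended the calls in dorsal striatum and in hippocampus. Gabbr2 was higher in amygdala, by 0.97 ± 0.17, and Arntl, the clock activator, higher in hippocampus, by 0.78 ± 0.14. Heyl, a Notch target, was higher in amygdala by 1.65 ± 0.23 (0.52 in batch 1 and 2.43 in batch 2), and Cspg4 and Pdgfra, genes of oligodendrocyte precursors, were higher there by 1.53 ± 0.36 and 1.33 ± 0.35, though not with the neuronal covariate (adjusted p = 0.088 and 0.178). The call of Pdgfra also ended in batch 2 alone and without amygdala 1, amygdala 2 and dorsal striatum 4. Rpl10a, the ribosomal protein that carries the tag in bacTRAP lines, was higher in prefrontal cortex by 0.65 ± 0.12, at 271 against 174 CPM, and not called with the oligodendrocyte covariate (0.14, adjusted p = 0.469).

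Genes that varied with the neuronal mean within regions and batches were more frequent among some sets. Of 547 genes at least 2-fold higher in dorsal striatum, 302 (55.2%) had r above 0.5 with it, as had 83 of 226 (36.7%) in ventral striatum, 252 of 760 (33.2%) in amygdala, 38 of 414 (9.2%) in hippocampus and 10 of 136 (7.4%) in prefrontal cortex, against 2273 of all 15355 (14.8%). Of genes at least 2-fold lower, 371 of 863 (43%) in prefrontal cortex, 234 of 474 (49.4%) in hippocampus, 21 of 72 (29.2%) in ventral striatum, 17 of 184 (9.2%) in dorsal striatum and 6 of 130 (4.6%) in amygdala did so. Of 1588 genes higher in amygdala, 449 (28.3%) were still called without amygdala 1, amygdala 2 and dorsal striatum 4, the libraries with the lowest astrocyte means but for ventral striatum 1.

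All 30 libraries had at least 301 counts of the Y-linked gene Ddx3y and at most 5 of Xist, while the design text speaks of male and female pools. Libraries of the batch 2 hippocampus differed from each other by 2.69 to 4.13 times sampling noise and those of the batch 2 prefrontal cortex by 4.55 to 11.17, against 14.36 to 144.98 for the other 8 groups of 3. Mitochondrially encoded genes had a median of −2.70 in hippocampus, 1.78 in dorsal striatum and 1.90 in amygdala, with mt-Nd1 in amygdala at 2.98 in batch 1 and 0.10 in batch 2.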
